A study of Mus musculus with 13 samples.

How the data were processed

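Liver RNA of 13 male mice was analysed, 7 mock-injected controls and 6 STZ-treated mice, with 1 Affymetrix mouse gene array per mouse. The groups and replicate numbers were taken from the labels, which call the arrays biological replicates. The sample labels and their protocol describe the controls as mock-injected with citrate buffer, while the series design text describes them by a standard diet and names no injection. The label numbers are 1 to 7 for the controls and 29, 30, 31, 32, 40 and 42 for STZ replicates 1 to 6, so the numbers of the groups do not overlap. No batch or date was given in the sources used here, and a batch that followed the numbers could not be told apart from the treatment. The deposited values are log2 intensities of 35556 probe sets, made with robust multi-array average (RMA) in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set, so an overall change in RNA amount per cell would not be seen. The annotation version and genome build used by the submitters are not given in the sources used here, and no coordinates are printed. The medians of the 13 arrays lay within 0.09 of each other, and no value was missing. The arrays carry no detection calls in the values used here, so a low value is read as low signal and not as absence, and differences of dim genes are compressed. The number of arrays limits the precision.

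Probe sets were named from the platform annotation, which gave 1 gene symbol for 21789 probe sets and several for 1621, and did not list 12146. Symbols were compared through their Entrez identifiers with the RefSeq table of the mouse assembly, in which 21698 of the 21789 were found and 0 needed a new symbol. Probe sets with several symbols or none named no gene. For each gene the probe set with the highest mean over all arrays was used, which gave 19938 genes, 998 of them with more than 1 probe set. No filter on dim genes was applied.

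The design, the gene lists and the rule for the genes named in the text were fixed before the data were examined. STZ was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, a 2-sided moderated test with 11 residual degrees of freedom before moderation, and the Benjamini-Hochberg adjustment over all 19938 genes with a threshold of 0.05. Differences are STZ minus control on the log2 scale, with the standard error of the fit. Gene lists (49, of which 23 were fixed as primary) were tested with camera at its preset inter-gene correlation of 0.01, adjusted together over the lists, and their members were counted over all genes and when adjusted over the list alone. Adjusted p values given for a list are those of camera at the preset correlation unless another test is named. Camera with an estimated correlation and fry were the alternatives, and an exact 2-sided permutation of the list mean over all 1716 splits, whose smallest p is 0.000583, was chosen after the data were seen. Of all the lists called at the preset correlation, only the periportal hepatocyte list was also called with an estimated correlation. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Lists overlap, and shared members are counted in each.

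The named genes were the 12 largest increases and the 12 largest decreases among the genes that passed, without predicted or unnamed models (62 of the 1819 genes that passed). Also named were 20 index genes of insulin action whatever their result, of which 18 were measured, and in each list up to 4 passing members with the largest absolute difference, or the member with the smallest p where none passed. Not every gene the rule allows is printed. The genes of the p53 pathway and the growth hormone target genes in the closing observations were chosen after the data were seen.

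The gene test was tested on simulated arrays with the mean of each real gene and 1 pooled spread for STZ and control arrays. Real spreads could differ between the groups, as for Slco1a1 (SD 0.10 in controls and 2.04 in STZ livers), which the simulation does not cover. Of 100 genes changed by 0.5 log2 units the gene test recovered 89%, and of 100 changed by 1 log2 unit 99%. There were 9 calls among the unchanged genes of 19938. Of 10 simulated lists of 20 genes, each gene raised by 0.5 log2 units, all 10 were called, and of 40 unshifted lists 0. Smaller or mixed shifts, such as the medians of 0.02 to 0.07 in the respiratory chain lists, were not simulated. How often camera would call those is therefore not known. The simulated genes varied independently of each other, while the estimated correlation in the real lists reached 0.749 (cholesterol synthesis). The simulation therefore cannot tell how often camera at the preset correlation wrongly calls a list of correlated genes.

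Alternatives were a filter for genes brighter than the median gene, a second quantile normalisation, centring each array on its median, the mean of all probe sets of a gene, eBayes with trend and robust variance, array weights, the replicate number as a block, only the STZ arrays with consecutive label numbers, all probe sets, an exact 2-sided rank-sum test, and leaving out each array in turn. Sex-biased members were also left out of the other lists, an alternative chosen after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. All 13 arrays and every column of the table were used.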

Results

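Gene expression was measured in the liver of male C57BL/6N wild-type mice that had received streptozotocin or a mock injection of citrate buffer. Streptozotocin (STZ) is a DNA-alkylating glucose analogue that destroys the insulin-producing beta cells of the pancreas and is used to induce insulin-deficient diabetes. It was given intraperitoneally at 65 mg/kg on 5 consecutive days to mice 10 to 16 weeks old, and livers were taken 9 to 11 weeks later, at an age of 5 to 6 months. Total RNA of 7 control and 6 STZ mice was hybridised to Affymetrix mouse gene arrays, 1 array per mouse, and the labels describe the arrays of a group as biological replicates. The series title names the question, which is how mitochondrial function of the liver is adapted in diabetic states. Each array gave 35556 values on a log2 scale, between 2.70 and 14.1, and 19938 named genes were compared. Across the 19938 named genes, Pearson correlations were 0.993 to 0.997 between control arrays and 0.986 to 0.995 between STZ arrays. Between a control and an STZ array they were 0.982 to 0.994. These correlations are across genes, not across independent replicates. Arrays carry no read depth, and their number limits the precision.

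In STZ livers, 20 of 22 male-biased genes, 20 of 25 genes of fatty acid and triglyceride synthesis and 8 of 20 of cholesterol synthesis were lower. Higher were 15 of 20 female-biased genes, 14 of 27 genes of amino acid catabolism, 10 of 26 antioxidant, 6 of 24 acute phase and 7 of 14 macrophage genes. These 8 lists passed in camera, a gene list test, at a preset correlation between genes, and none of them with an estimated correlation (adjusted p = 0.0782 to 0.402). The periportal hepatocyte list, with 7 of 13 genes higher, was the only list called in both (adjusted p = 5.60e-07 and 0.0400 in camera). Most genes of the respiratory chain showed no change that passed the test. Of the 19938 genes, 1819 (9.12%) passed at an adjusted p under 0.05 in limma. Of these, 1014 were higher and 805 lower in STZ livers, and 139 differed at least 2-fold, 59 of them higher and 80 lower. The values of the 7 controls and the 6 STZ arrays did not overlap for 770 of the 19938 genes, where chance alone gives about 23.2 (0.117%). At an unadjusted p under 0.05 there were 4156 genes. The median difference of all genes was -0.01 on the log2 scale, and the median standard error was 0.07.

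The largest increase was that of Cyp2b9, a female-predominant cytochrome P450, which rose by 5.89 ± 0.58 on the log2 scale (difference ± SE of the fit, as for all values below), from 6.42 ± 1.13 (SD, n = 7) in controls to 12.31 ± 1.43 (SD, n = 6). It was followed by the estrogen sulfotransferase Sult1e1 (4.64 ± 0.70), the P450 genes Cyp2b10 (3.83 ± 0.30), Cyp2b13 (3.33 ± 0.47) and Cyp2a22 (3.14 ± 0.38), and the metallothioneins Mt2 (3.81 ± 0.26) and Mt1 (3.05 ± 0.32), which bind zinc and other metals. The acute phase genes Lcn2 (3.21 ± 0.40), Orm2 (2.90 ± 0.25) and Orm3 (2.73 ± 0.34), the organic anion transporter gene Slc22a26 (2.82 ± 0.57) and Ly6d (2.61 ± 0.38) completed the 12 largest increases. The largest measured decrease was that of Hsd3b5, a male-specific hydroxysteroid dehydrogenase, which fell by 5.92 ± 0.70, from 11.68 ± 0.29 (SD, n = 7) to 5.76 ± 2.23 (SD, n = 6). In 5 of the 6 STZ arrays it lay between 4.71 and 5.03, near the lower quartile of all probe sets (4.88 to 4.94 in the STZ arrays). Next came Serpina4-ps1 (-5.45 ± 0.36), the organic anion transporter Slco1a1 (-5.03 ± 0.63), the fatty acid elongase Elovl3 (-4.50 ± 0.81), Cyp4a12a (-3.05 ± 0.65) and Cyp4a12b (-2.70 ± 0.66), and the N-acetyltransferase Nat8f5 (-2.75 ± 0.56). The remaining decreases among the 12 largest were the deiodinase Dio1 (-2.73 ± 0.40), the major urinary protein Mup21 (-2.63 ± 0.45), the taurine synthesis enzyme Csad (-2.50 ± 0.20), the lipogenic regulator Thrsp (-2.36 ± 0.33) and the water channel Aqp8 (-2.23 ± 0.33). Probes of close paralogs in the Cyp2b, Cyp4a12, Orm and Mup families can cross-hybridise, so the values of single members are uncertain. Cyp2b9, Sult1e1, Cyp2b13, Slc22a26 and Ly6d in controls, and Hsd3b5, Serpina4-ps1, Slco1a1 and Mup21 in STZ livers, lay under the median gene, where arrays compress differences, so their sizes and order are uncertain. Cyp4a12b did not pass in limma with trend and robust variance (adjusted p = 0.0614).

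Genes with a sex bias in mouse liver held the largest differences. Of 22 measured male-biased genes, 20 fell and none rose (0 higher and 21 lower when adjusted over the list alone), with a median difference of -1.38 and an adjusted p of 1.77e-21 in camera. Of 20 measured female-biased genes, 15 rose and none fell (17 higher and 0 lower adjusted over the list alone), with a median of 1.06 and an adjusted p of 1.92e-19. The adjusted p was 0.106 for the male-biased and 0.0782 for the female-biased list in camera with an estimated correlation, so neither call held there. Examples were Hsd3b5, Slco1a1, Elovl3 and Cyp4a12a among the male-biased genes and Cyp2b9, Sult1e1, Cyp2b10 and Cyp2b13 among the female-biased genes. The list means of 6 of 6 STZ arrays lay beyond all 7 controls in both lists. STZ replicate 5 lay closest to the controls, with a mean of 10.96 for the male-biased list against a lowest control of 11.02. In that array Hsd3b5 was 10.31. Without it the Hsd3b5 difference was -6.83 and the Slco1a1 difference -5.86.

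**Figure D1:**
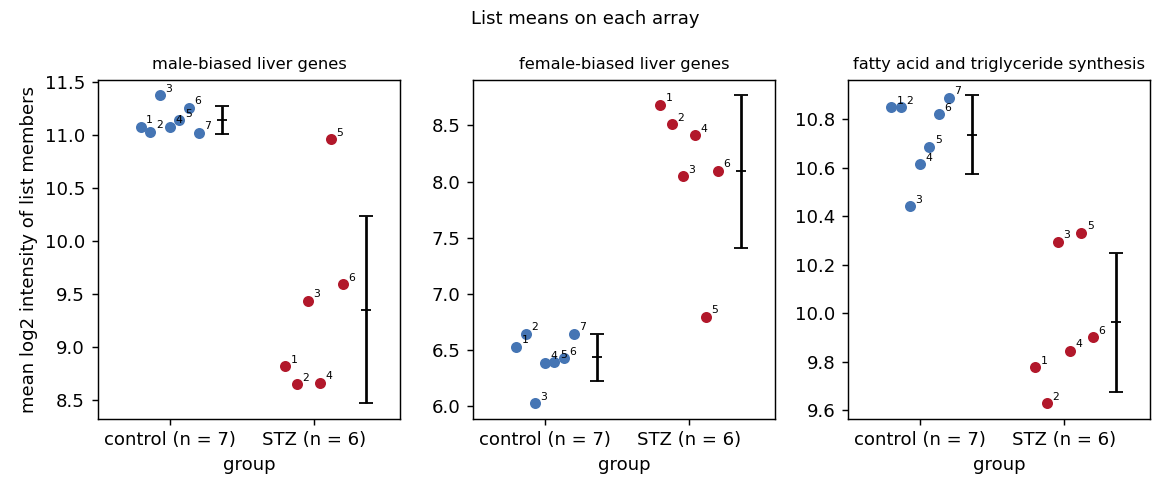
Mean log2 intensity of the members of 3 gene lists (y axis) on each array of the control (blue) and STZ (red) groups (x axis), with numbers giving the replicate and the bar beside each group giving its mean ± SD. In the male-biased list the STZ arrays lay between 8.65 and 10.96 and the controls between 11.02 and 11.37, in the female-biased list between 6.80 and 8.68 against 6.02 to 6.65, and in the fatty acid and triglyceride synthesis list between 9.63 and 10.33 against 10.44 to 10.89.

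Index genes of insulin action in the liver were examined whatever their result, and 18 of the 20 chosen were measured. Igfbp1, a secreted IGF-binding protein that insulin represses, rose by 2.51 ± 0.34, from 7.77 ± 0.61 (SD, n = 7) to 10.28 ± 0.87 (SD, n = 6). The gluconeogenic enzyme gene Pck1 (0.59 ± 0.10), the insulin receptor substrate Irs2 (0.66 ± 0.11), the coactivator Ppargc1a (0.91 ± 0.17) and the fatty acid omega-hydroxylase Cyp4a14 (1.13 ± 0.28) were also higher. The lipogenic transcription factor Srebf1 (-0.71 ± 0.15), fatty acid synthase Fasn (-1.30 ± 0.24), the desaturase Scd1 (-0.79 ± 0.16) and liver pyruvate kinase Pklr (-1.20 ± 0.23) fell. The differences of Insr (0.09 ± 0.07), Pdk4 (0.22 ± 0.34), Cpt1a (-0.13 ± 0.09), Fgf21 (-0.16 ± 0.07), Cyp7a1 (-0.32 ± 0.21), Igf1 (-0.03 ± 0.06) and Txnip (-0.10 ± 0.10) did not pass. G6pc, the glucose-6-phosphatase gene, was -0.37 ± 0.13 with an adjusted p of 0.103, and Cyp8b1, which directs bile acid synthesis to cholic acid, was -1.01 ± 0.37 with an adjusted p of 0.113. Without STZ replicate 5 or STZ replicate 6, Cyp8b1 passed in limma with adjusted p of 0.0375 and 0.0437, while without STZ replicate 2 it was -0.65 and did not pass. Without STZ replicate 2 G6pc was -0.25. With only the 4 STZ arrays of consecutive label numbers, Cyp8b1 was -1.58 (adjusted p = 0.00335) and G6pc -0.51 (0.0332). Without control replicate 6 Fgf21 passed at 0.0156, and with trend and robust variance Cyp4a14 did not pass (0.0579).

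Fatty acid and triglyceride synthesis was the metabolic list with the most members lower in STZ livers. Of its 25 measured genes, 20 fell and none rose (1 higher and 21 lower adjusted over the list alone), with a median of -0.71 and an adjusted p of 5.10e-19, which was 0.0794 with an estimated correlation. The list mean lay below all 7 controls in 6 of 6 STZ arrays. Besides Thrsp and Fasn, malic enzyme Me1 (-1.95 ± 0.29), the acyltransferase Gpam (-1.42 ± 0.12) and the acetyl-CoA carboxylase Acacb (-1.37 ± 0.23) were among the lower genes. Cholesterol synthesis genes were lower for 8 of 20, with none higher (1 higher and 12 lower adjusted over the list alone), at a median of -0.36 and an adjusted p of 2.36e-08. The adjusted p was 0.402 with an estimated correlation and 0.0572 in fry. Examples were the sterol carrier Stard4 (-0.62 ± 0.11), the sterol dehydrogenase Nsdhl (-0.60 ± 0.13) and the SREBP retention factor Insig1 (-0.57 ± 0.10). Without STZ replicate 2 the median of the cholesterol list was -0.17, and its call held.

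Of 27 measured genes of amino acid catabolism and the urea cycle, 14 were higher and none lower (19 and 0 adjusted over the list alone), with a median of 0.22 and an adjusted p of 9.61e-13. With an estimated correlation the adjusted p was 0.0970. The list mean lay above all controls in 6 of 6 STZ arrays. Examples were cystathionine gamma-lyase Cth (0.96 ± 0.08), the glyoxylate aminotransferase Agxt (0.81 ± 0.16), the lysine-degrading enzyme Aass (0.74 ± 0.08) and the mitochondrial ornithine carrier Slc25a15 (0.61 ± 0.08). Gluconeogenesis genes were higher for 4 of 15 (6 higher and 1 lower adjusted over the list alone), at a median of 0.09 and an adjusted p of 0.00359, which was 0.366 with an estimated correlation. Its 4 higher members were Ppargc1a, Pck1 and the aminotransferases Got1 (0.58 ± 0.08) and Gpt (0.38 ± 0.08). It shares 4 genes with the amino acid list, and its mean lay above all controls in 3 of 6 STZ arrays. Of 15 glycolysis genes, Tpi1 (0.20 ± 0.05) was higher and Pklr and the carbohydrate-responsive factor Mlxipl (-0.44 ± 0.12) were lower (the same counts, 1 and 2, adjusted over the list alone). The glycolysis median was 0.02 while its mean was -0.10 and its test pointed down, with an adjusted p of 0.903. Mlxipl lost its call in 6 of the 13 fits that left out an array. Glycogen metabolism had 1 gene higher and 4 lower of 14 (4 and 6 adjusted over the list alone), among them Ugp2 (0.47 ± 0.08), the glycogen-targeting phosphatase subunit Ppp1r3b (-0.83 ± 0.16) and liver glycogen synthase Gys2 (-0.43 ± 0.09). Its median was 0.07, its mean -0.01 with the test pointing down, and its adjusted p 0.903. In the insulin signalling list 4 of 22 were higher and 1 lower (4 and 3 adjusted over the list alone), including Irs1 (0.50 ± 0.10) and the PI3-kinase regulatory subunit Pik3r1 (-0.68 ± 0.09), with a median of 0.02 and an adjusted p of 0.547.

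**Figure D2:**
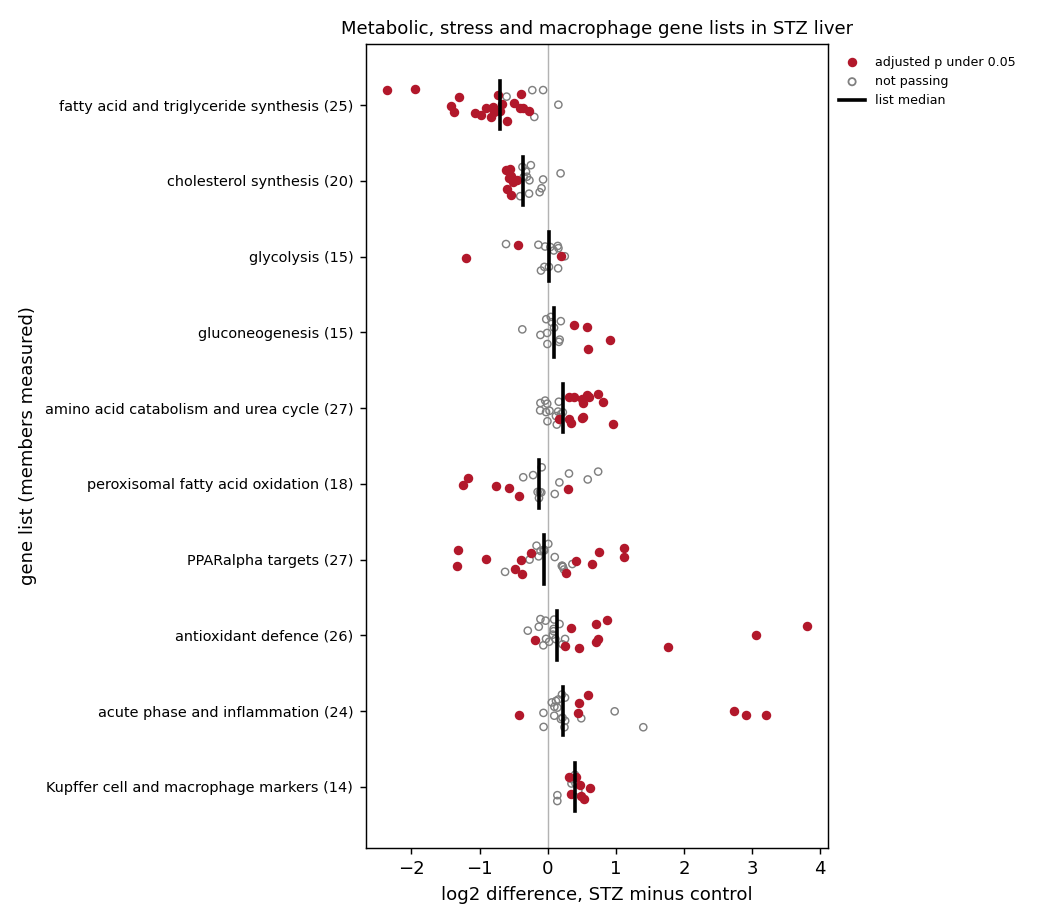
Log2 difference between STZ and control livers (x axis) of each measured member of 10 gene lists (y axis, number of members in parentheses), with filled points for genes that passed the test, open points for the others, and a bar at the list median. In fatty acid and triglyceride synthesis 20 of 25 members were lower (median -0.71), and in amino acid catabolism and urea cycle 14 of 27 were higher (median 0.22).

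Transcripts of the mitochondrial respiratory chain showed few changes. In complex I, 1 of 35 genes was higher and 1 lower, Ndufa7 (0.19 ± 0.05) and Ndufb3 (-0.22 ± 0.06), and each lost its call in 9 of the 13 fits that left out an array. No complex I gene passed when adjusted over the list alone, the median was 0.02 and the adjusted p 0.468. No gene of complex II (4 measured, median 0.07, adjusted p = 0.407), complex III (9 measured, 0.02, 0.879) or complex IV (11 measured, 0.04, 0.688) passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 0 and 1 genes, and the exact rank-sum test called 0. The smallest p values there belonged to Sdhc (0.10 ± 0.05), Uqcrfs1 (0.16 ± 0.09) and Cox7a2l (-0.12 ± 0.05). In complex V, 1 of 16 genes was higher (also 1 adjusted over the list alone), Atpif1 (0.45 ± 0.08), the inhibitor of ATP synthase, with a list median of 0.05 and an adjusted p of 0.338. The 2 mitochondrially encoded genes measured, ND3 (0.02 ± 0.05) and COX2 (0.00312 ± 0.0426), did not pass in limma, also at an unadjusted p under 0.05, and the rank-sum test called 0 (list median 0.00976, adjusted p = 0.903). Of 75 mitochondrial ribosome genes 1 was higher, Mrpl40 (0.17 ± 0.05), which lost its call in 11 of 13 such fits, and none passed adjusted over the list alone (median -0.02, adjusted p = 0.755). The biogenesis and dynamics list had 1 of 25 higher, Ppargc1a, and 1 lower, the transcription factor Gabpa (-0.23 ± 0.05), with the same counts adjusted over the list alone. Its median was -0.01 with the test pointing down and its mean 0.01, at an adjusted p of 0.763.

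Tricarboxylic acid cycle genes were the mitochondrial list that passed. Of 18 measured, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), at a median of 0.08 and an adjusted p of 0.00225. The adjusted p was 0.463 with an estimated correlation, 0.0747 in fry and 0.0538 in an exact permutation of the list mean. Isocitrate dehydrogenase Idh2 (0.64 ± 0.09), fumarase Fh1 (0.56 ± 0.12) and the oxoglutarate dehydrogenase subunit Ogdh (0.34 ± 0.07) were higher, and citrate synthase Cs was -0.30 ± 0.09, a call lost in 10 of the 13 fits that left out an array. Without control replicate 2 the list median was 0.05. The list mean lay above all controls in 4 of 6 STZ arrays. Among mitochondrial fatty acid oxidation genes, 3 of 21 were lower and none higher (1 higher and 3 lower adjusted over the list alone), with a median of -0.02 and an adjusted p of 0.547. They were Eci1 (-0.34 ± 0.07), the carnitine-acylcarnitine carrier Slc25a20 (-0.31 ± 0.08) and Acaa2 (-0.16 ± 0.05), and Slc25a20 lost its call in 5 and Acaa2 in 10 of 13 such fits. Of 14 uncoupling proteins and carriers, 2 were higher, the glutamate carriers Slc25a22 (0.63 ± 0.13) and Slc25a12 (0.43 ± 0.09), and 1 was lower, Slc25a47 (-0.37 ± 0.10), which lost its call in 6 of 13 fits. The counts were the same adjusted over the list alone, the median was 0.06 and the adjusted p 0.295.

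**Figure D3:**
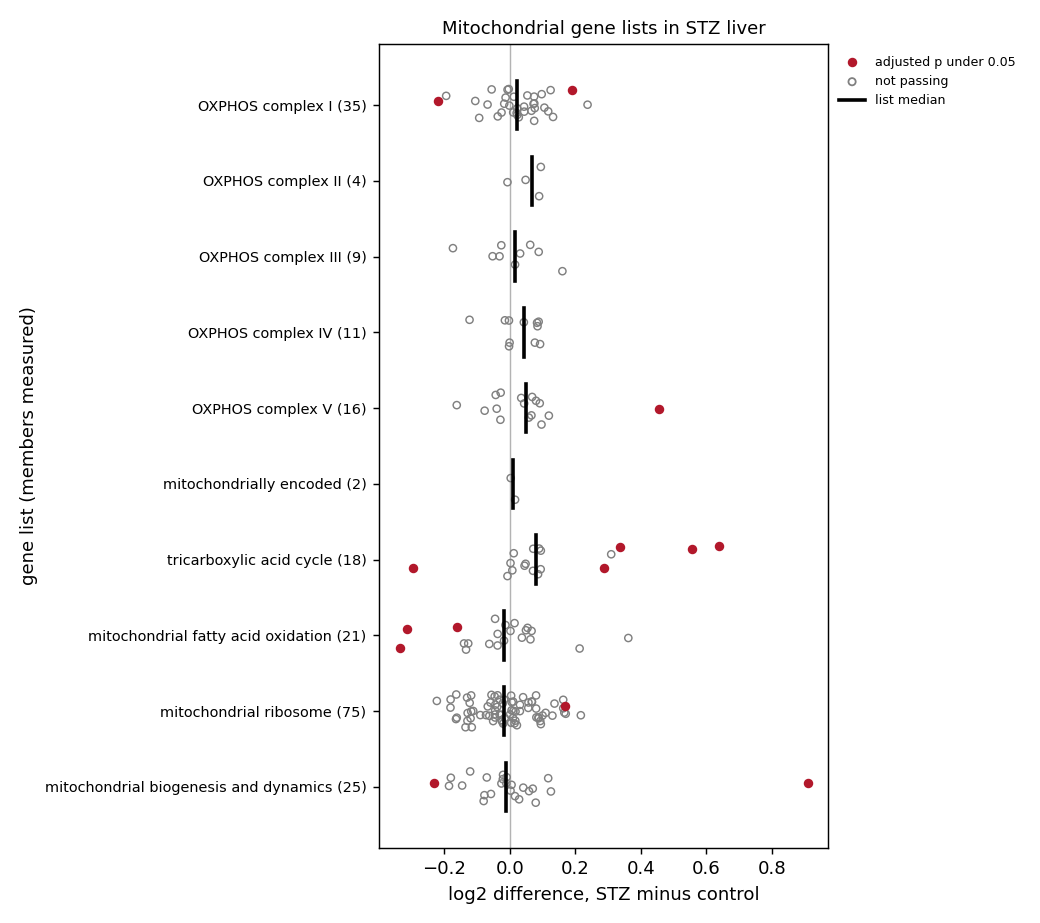
Log2 difference between STZ and control livers (x axis) of each measured member of 10 mitochondrial gene lists (y axis, number of members in parentheses), with filled points for genes that passed the test, open points for the others, and a bar at the list median. The medians of complexes I to V lay between 0.02 and 0.07, and that of the tricarboxylic acid cycle list was 0.08. Over the fits that left out an array, the median went from 0.01 to 0.05 in complex I, 0.03 to 0.08 in complex II, -0.00383 to 0.03 in complex III, -0.00191 to 0.08 in complex IV and 0.02 to 0.06 in complex V.

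Peroxisomal fatty acid oxidation genes were lower for 5 of 18 and higher for 1 (7 lower and 1 higher adjusted over the list alone), at a median of -0.12 and an adjusted p of 0.00278. The adjusted p was 0.343 with an estimated correlation and 0.0639 in the exact permutation of the list mean. The list mean lay below all controls in 2 of 6 STZ arrays. The thiolase Acaa1b (-1.24 ± 0.17), the peroxisome proliferation factor Pex11a (-1.17 ± 0.13), the sterol carrier protein gene Scp2 (-0.77 ± 0.15) and the fatty acid transporter Abcd3 (-0.57 ± 0.10) were among the lower genes. Ketone body synthesis had 2 measured genes, of which Acat1 (-0.50 ± 0.09) fell (2 lower adjusted over the list alone), at a median of -0.35 and an adjusted p of 0.0290. This was 0.305 with an estimated correlation, 0.0576 without STZ replicate 2, and 0.0828 among genes brighter than the median gene. Targets of the nuclear receptor PPARalpha went both ways, with 6 of 27 higher and 7 lower (6 and 8 adjusted over the list alone), a median of -0.05 and an adjusted p of 0.860. Cyp4a14 and Cyp4a31 (1.12 ± 0.13), which are close paralogs, were higher, while the lipid droplet gene Cidec (-1.34 ± 0.18) and the fatty acid-binding protein Fabp1 (-1.31 ± 0.25) were lower. Bile acid synthesis and transport genes also went both ways, with 6 of 22 higher and 5 lower (6 and 6 adjusted over the list alone). The bile acid transporters Slco1a4 (1.89 ± 0.20) and Slc51b (1.22 ± 0.15) were higher and Slco1a1 and the oxysterol hydroxylase Cyp7b1 (-1.49 ± 0.26) lower. Its median was -0.02 and its mean -0.14 while its test pointed up, with an adjusted p of 0.695. Lipoprotein and lipid transport had 4 of 19 higher and 5 lower (5 and 5 adjusted over the list alone), a median of 0.01 with a mean of -0.01, and an adjusted p of 0.903. It held phospholipid transfer protein Pltp (-1.94 ± 0.15) and lipoprotein lipase Lpl (0.83 ± 0.21), and Lpl lost its call in 2 of the 13 fits that left out an array and with trend and robust variance (adjusted p = 0.0628).

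Lists of stress and defence genes were also tested. Of 26 antioxidant genes, 10 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 0.14 and an adjusted p of 3.92e-07. With an estimated correlation the adjusted p was 0.0782. Besides Mt2 and Mt1, the quinone reductase Nqo1 (1.76 ± 0.24) and the glutathione transferase Gstm3 (0.88 ± 0.11) were higher. Acute phase and inflammation genes were higher for 6 of 24 and lower for 1 (9 and 1 adjusted over the list alone). Among the members that passed, Lcn2, Orm2, Orm3 and Itih3 (0.60 ± 0.15) moved most. The median was 0.23 and the adjusted p 1.44e-07, which was 0.336 with an estimated correlation. Without STZ replicate 2 the median was 0.13, and the call held. Kupffer cell and macrophage markers were higher for 7 of 14 in the same livers, at a median of 0.40 (adjusted p = 0.305 with an estimated correlation), and the exact rank-sum test called 0 of them. Interferon response genes were higher for 5 of 19 (12 higher adjusted over the list alone), led by Usp18 (1.27 ± 0.14) and the guanylate-binding protein Gbp3 (0.83 ± 0.14). Their median was 0.25 and the adjusted p 6.01e-07, which was 0.305 with an estimated correlation. Their mean lay above all controls in 4 of 6 STZ arrays. Of 27 xenobiotic cytochromes P450, 13 were higher and 2 lower (15 and 2 adjusted over the list alone), at a median of 0.23 and an adjusted p of 4.22e-08, which was 0.0782 with an estimated correlation. Of these, 7 genes also belong to the sex-biased lists, and for the other 20 the median was 0.17 and the adjusted p 0.00114. In the unfolded protein and stress response list, 1 of 23 was higher and 4 lower (1 and 6 adjusted over the list alone), with Herpud1 at -0.49 ± 0.14, Dnajb9 at -0.27 ± 0.07 and Trib3 at 0.41 ± 0.09. The median was -0.14 and the adjusted p 0.0236, which was 0.463 with an estimated correlation, 0.0908 in fry and 0.212 in the exact permutation of the list mean. The call was lost without control replicate 3 (adjusted p = 0.0784) and without STZ replicate 2 (0.0736), and that of Herpud1 in 8 of the 13 fits that left out an array. The list mean lay below all controls in 1 of 6 STZ arrays.

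Markers of cell types other than hepatocytes were measured in the same tissue. Kupffer cell and macrophage markers were higher for 7 of 14 and lower for none (12 and 0 adjusted over the list alone), with a median of 0.40 and an adjusted p of 2.82e-08, which was 0.305 with an estimated correlation. The scavenger-receptor protein Cd5l (0.62 ± 0.15), Cd163 (0.53 ± 0.14), the complement component C1qc (0.49 ± 0.13) and Cd68 (0.47 ± 0.13) were higher, and 6, 6 and 7 of the 13 fits that left out an array lost the calls of Cd163, C1qc and Cd68. The list mean lay above all controls in 5 of 6 STZ arrays. It shifted by 0.31 ± 0.10 more than the mean of the endothelial, stellate and T cell lists (exact 2-sided permutation p = 0.0128), a comparison chosen after the data were seen. Lists left out of that comparison included cholangiocyte (mean shift 0.20), neutrophil (0.11) and B cell markers (-0.07), and the size of the excess depends on this choice. Endothelial markers were higher for 2 of 13, Lyve1 (0.50 ± 0.11) and Eng (0.21 ± 0.06, lost in 6 of 13 fits), with 2 adjusted over the list alone, a median of 0.09 and an adjusted p of 0.0512. The endothelial list passed after a second quantile normalisation (0.0455) and without STZ replicate 2 (0.0139), STZ replicate 3 (0.0303), control replicate 6 (0.0383) or control replicate 7 (0.0236), and its median was 0.06 without STZ replicate 4. Stellate cell and fibroblast markers were higher for 3 of 13 and lower for 1, with the same counts adjusted over the list alone. These were the matrix proteins Lum (0.86 ± 0.13) and Dcn (0.35 ± 0.06), Timp1 (0.34 ± 0.08) and the retinol-storing enzyme Lrat (-0.47 ± 0.08), at a median of 0.05 and an adjusted p of 0.0986. The stellate list passed without control replicate 4 (0.0418) and without STZ replicate 3 (0.0382, at a median of 0.09), and its median was 0.03 without STZ replicate 1. Cholangiocyte markers were higher for 1 of 9 (4 adjusted over the list alone), Tspan8 (0.25 ± 0.07, lost in 9 of 13 fits), at a median of 0.16 and an adjusted p of 0.0290. This was 0.463 with an estimated correlation, 0.0913 in fry, 0.0792 in the exact permutation of the list mean and 0.0705 with only the STZ arrays of consecutive label numbers. The cholangiocyte list mean lay above all controls in 2 of 6 STZ arrays. The call was also lost without control replicate 7, STZ replicate 1 or STZ replicate 6 (adjusted p of 0.0507, 0.0831 and 0.0528) and among genes brighter than the median gene (0.626). The median was 0.08 without STZ replicate 4, 0.24 without control replicate 4, and 0.32 over the members brighter than the median gene. Neutrophil markers had none of 12 passing in limma, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, 0 in the rank-sum test), at a median of 0.13 and an adjusted p of 0.0452. This was 0.494 with an estimated correlation, 0.118 in fry, 0.0999 in the exact permutation of the list mean and 0.0869 with array weights. The neutrophil call was lost in 7 of the 13 fits that left out an array, with an adjusted p of up to 0.161, and the median was 0.09 without STZ replicate 4. The neutrophil list mean lay above all controls in 2 of 6 STZ arrays. T and NK cell markers had 1 of 13 lower, Cd4 (-0.23 ± 0.06, lost in 6 of 13 fits), at a median of 0.01 with the test pointing down and an adjusted p of 0.903, and B cell markers 1 of 7, Cd79b (-0.40 ± 0.10), at a median of -0.03 and an adjusted p of 0.468, each also 1 adjusted over the list alone. Of 9 hepatocyte markers, 1 was higher and 2 lower (3 and 2 adjusted over the list alone), at a median of 0.05 and an adjusted p of 0.727.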

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

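The tests on Xist, on the growth hormone targets, on the level of the 28 p53 targets in STZ replicate 5 and on other splits of the arrays were chosen only after the results were seen. The tests of dilution, of a weaker loss of insulin action and of the other p53 targets had their predictions written before their values were looked up.

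Within each group, a list mean or a named gene was looked at again where 1 array lay far from the others (Dixon's test). This was so in 27 of 366 groups of arrays, where chance alone gives about 18.3 (5%), so most single cases are within what chance gives. STZ replicate 5 was the stray array in 9 of them. Its values lay toward the controls for the female-biased list mean (6.80, the other STZ arrays 8.05 to 8.68), Cyp2b9 (9.40), Hsd3b5 (10.3), Serpina4-ps1 (8.32), Slco1a1 (10.3), Cyp4a14 (12.5), Cyp7b1 (11.5) and Pltp (9.66), and its pancreatic acinar list mean was 5.61 where the other STZ arrays were at 5.79 to 5.89. On the first principal component, which held 44.9% of the variance, it lay at -2.02 (its label number is 40, apart from the consecutive 29 to 32), between the controls (-15.8 to -14.6) and the other STZ arrays (11.3 to 28.7).

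STZ replicate 5 thus had means of the sex-biased lists close to control levels, though Cyp2b9 was 9.40 there against a control mean of 6.42. For its position 3 explanations were weighed. A control array carrying the STZ label is argued against by the 28 p53 targets listed before their values were looked up, whose mean lay 0.424 above the highest control, where the whole control range was 0.118. Dilution with control liver RNA would keep an equal share of every shift, but the median share kept was 0.954 for 21 p53 targets and 0.0367 for 18 female-biased genes, a difference of 0.917. The p53 share was also 0.954 over the 17 of them that were not picked from the table of all genes. Shares were taken on the linear scale, over members that shifted by at least 0.3 log2 units in the other STZ arrays. Shares on the log2 scale were not computed and can differ, so the readings of shares hold for the linear scale only. A weaker loss of insulin action in this mouse may be part of it, but the share of the shift kept in fatty acid and triglyceride synthesis was 0.609, between the values that would have spoken for it or against it, so this stays open. It was 0.561 in amino acid catabolism, 0.624 in macrophage markers, 0.365 in antioxidant defence, 0.286 in cholesterol synthesis, 0.161 in the acute phase and 0.125 in male-biased genes, so the smaller shift was not limited to sex-biased transcripts. No blood glucose or insulin value was used here.

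The shift of sex-biased genes toward the female pattern was weighed against 2 explanations. Female mice among the STZ arrays are argued against by Xist, whose highest STZ value was -0.04 relative to the highest control. For a general loss of growth hormone signalling, which may account for such a pattern, the values were mixed. The mean of Igf1, Igfals, Socs2 and Cish shifted by 0.0167 ± 0.166 (SE between arrays, 7 and 6 arrays), so these genes did not fall as a set. Igfals was lower (-0.43 ± 0.12), while Igf1 (-0.03 ± 0.06), Socs2 (0.26 ± 0.23) and Cish (0.27 ± 0.33) did not pass. Because 1 member fell and the others did not, a loss cannot be told apart from no loss here. Hormone levels and the pulse pattern of growth hormone were not analysed here, and the effect of the STZ treatment itself stays open.

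STZ replicate 2 had the lowest cholesterol synthesis mean (9.57, other STZ arrays 10.1 to 10.5) and the highest acute phase mean (10.9, others 9.74 to 10.2). In single lists, the female-biased mean was 6.02 in control replicate 3, the proteasome mean 9.91 in control replicate 2, and the hepatocyte marker mean 12.8 in STZ replicate 3. Control replicate 4 had a stellate cell mean of 7.81 and a cholangiocyte mean of 6.14, both the highest of the controls. Among single genes, control replicate 2 was apart for Irs2 (7.77), Insr (9.88), Slc25a20 (10.4), Acaa2 (12.99) and Uqcrfs1 (8.38), and control replicate 3 for Cyp4a14 (10.1), Cyp4a31 (10.2) and Slc25a47 (11.1). Fgf21 was 5.54 in control replicate 6, Usp18 was 9.00 in control replicate 5, and Cidec was 7.00 in STZ replicate 4.

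Of the 13768 probe sets outside the gene table, which had no listed gene or several, 153 were higher and 127 lower in STZ livers in limma over all probe sets, and none of them is named here.

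A gene count that any grouping of the arrays would give is argued against. Of 100 splits of the 13 arrays into 7 and 6, the real one included, 1 gave as many genes as the 1819 of the real split, and the highest of the others gave 13.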

How the results depend on the processing

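The exact permutation of list means was added after the data were seen. The alternatives that refit limma over genes kept the direction of all of the 1819 genes (of the 1533 tested under the brightness filter), and the counts lay between 1685 and 1986 for the filter, scalings, probe set mean, variance model, array weights and consecutively numbered STZ arrays. All of them reuse the same arrays, and trend and robust variance leave the differences themselves unchanged. Kept directions are therefore no independent support. Testing all probe sets called 1637, and their directions were not compared with the gene fit. Leaving out an array gave 1399 (without STZ replicate 4) to 2168 genes (without STZ replicate 5), 761 to 1146 higher and 625 to 1022 lower. The exact rank-sum test called 1088 genes, 623 higher and 465 lower, of which 1015 were among the 1819. Its smallest possible p is 0.000583, which limits what it can call.

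Same-numbered arrays shared only a number, with correlations of deviations of 0.11, 0.19, 0.04, -0.05, 0.03 and -0.09, and 1 of 6 STZ arrays correlated best with the control of its own number. The replicate block, which used 12 of the arrays, called 1256 genes, 732 higher and 524 lower, and 26 named genes that had passed did not pass with it. In camera with it the endothelial (adjusted p = 0.0236) and stellate lists (0.0462) passed and the neutrophil list (0.0624) did not.

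With an estimated correlation the adjusted p was 0.463 for the tricarboxylic acid cycle, 0.343 for peroxisomal oxidation, 0.305 for ketone body synthesis, 0.366 for gluconeogenesis, 0.0794 for fatty acid and triglyceride synthesis, 0.402 for cholesterol synthesis, 0.0970 for amino acid catabolism, 0.0782 for antioxidant defence, 0.463 for the unfolded protein response, 0.336 for the acute phase, 0.0782 for cytochromes P450, 0.106 for male-biased and 0.0782 for female-biased genes. In fry it was 0.0747 for the tricarboxylic acid cycle, 0.0572 for cholesterol synthesis and 0.0908 for the unfolded protein response. In the exact permutation of list means it was 0.0538, 0.0639 and 0.212 for the tricarboxylic acid cycle, peroxisomal oxidation and the unfolded protein response, and 0.0286 for glycolysis, which passed there. The glycolysis mean shift was -0.10 while its median was 0.02, so that call is not a shift of most members. The ketone list kept a median of -0.353 among genes brighter than the median gene at an adjusted p of 0.0828. Leaving out an array gave it -0.401 to -0.270, and the unfolded protein response -0.199 to -0.0937. Medians near 0 moved with single arrays, such as those of glycolysis (-0.02 to 0.05), cell cycle (-0.11 to 0.03), T and NK cell (-0.08 to 0.06) and pericentral genes (0.02 to 0.08), and none of these lists passed in camera in any such fit. The cause was not tested for any of these. Of 129 named genes that passed, 103 passed in each fit without 1 array and 26 lost the call in at least 1. Of named genes that passed, trend and robust variance ended 8 calls (among them Cyp4a12b, Cyp4a14, Bcl6, Lpl and Herpud1), median centring 7 (Ndufb3, Cs and Acaa2 among them), array weights 3 (Mrpl40 and Slc25a47 among them), a second quantile normalisation 2 and the consecutively numbered STZ arrays 12 (C1qc, Cd68, Eng, Cd4 and Bhlhe40 among them). No value that had passed changed sign in these refits of the same arrays. Without detection calls, signal over background could not be tested.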

Other observations

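Hepatocyte zonation, growth hormone and cell cycle lists were also tested, and of these the periportal list passed. Periportal hepatocyte genes were higher for 7 of 13 and lower for none (10 and 0 adjusted over the list alone), with a median of 0.26 and an adjusted p of 5.60e-07 in camera, which was 0.0400 with an estimated correlation. The list mean lay above all controls in 6 of 6 STZ arrays. Examples were the steroid dehydrogenase Hsd17b6 (0.92 ± 0.12), the protease cathepsin C gene Ctsc (0.84 ± 0.09) and the histidine-degrading enzyme Hal (0.51 ± 0.07), and 4 members also belong to the amino acid list. Of 17 pericentral genes, 4 were higher and 2 lower (5 and 2 adjusted over the list alone), at a median of 0.04 and an adjusted p of 0.407. In the growth hormone and IGF list, 2 of 14 were higher and 3 lower, with the same counts adjusted over the list alone. These were Igfbp1, Igfbp2 (0.93 ± 0.12), the repressor Bcl6 (-1.37 ± 0.33, adjusted p = 0.0535 with trend and robust variance), the receptor Ghr (-0.57 ± 0.10) and Igfals, at a median of 0.05 and an adjusted p of 0.835. The cell cycle list had 1 of 26 higher, cyclin D1 (Ccnd1, 1.93 ± 0.22), also 1 adjusted over the list alone, at a median of -0.04, a mean of 0.02 and an adjusted p of 0.695.

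The remaining lists did not pass in camera at the preset correlation. Of 18 circadian clock genes, 1 was lower, Bhlhe40 (-0.56 ± 0.14, lost in 2 of the 13 fits that left out an array and with only the STZ arrays of consecutive label numbers), also 1 adjusted over the list alone, at a median of -0.22 and an adjusted p of 0.295. Without control replicate 6 the circadian median was -0.08. Cytosolic ribosome genes had 1 of 48 lower and a median of -0.000976 (adjusted p = 0.842), proteasome genes 0 of 31 and a median of 0.03 (0.903), and pancreatic acinar markers 0 of 11 and a median of -0.0016 (0.763). Adjusted over the list alone, none of the ribosome, proteasome or acinar genes passed in limma, where 3, 1 and 0 were at an unadjusted p under 0.05, and the exact rank-sum test called 0. Mesothelial markers had 1 of 6 higher, Krt8 (0.43 ± 0.09), also 1 adjusted over the list alone, at a median of -0.05 and a mean of 0.02 (0.903). Erythroid markers had 1 of 3 lower, the heme synthesis gene Alas2 (-1.58 ± 0.26), also 1 adjusted over the list alone, at a median of -0.05 (-0.01 without control replicate 2) and an adjusted p of 0.280, and adipocyte markers 1 of 8 higher, Fabp4 (0.58 ± 0.10), and 3 lower, including Cidec (2 and 4 adjusted over the list alone), at a median of -0.16 and an adjusted p of 0.151. The list means of 6 of 6 STZ arrays lay beyond all 7 controls in the erythroid and the adipocyte list. The adjusted p was 0.00286 for the erythroid and 0.00476 for the adipocyte list in the exact permutation of the list mean, and 0.0463 and 0.00295 in fry. The erythroid mean shift was -0.52 over 3 genes, against a median of -0.05 and an Alas2 difference of -1.58. These erythroid results therefore largely reflect Alas2 and not a shift of the whole list.

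Several p53 target genes were higher in STZ livers, a pattern noticed in the table of all genes. Phlda3 (1.98 ± 0.08), Eda2r (1.93 ± 0.13), Ddias (1.61 ± 0.16) and Btg2 (2.30-fold) were higher, and were picked because they were. The hypothesis that p53 targets rose as a group was tested on 30 other known targets, listed before their values were looked up, of which 28 were measured. Their mean shifted by 0.44 ± 0.03 (SE between arrays), with an exact permutation p of 0.000583, the smallest the 1716 splits can give. The mean of these 28 was 7.86 to 8.03 in the STZ arrays and 7.47 to 7.58 in the controls. Of the 28, 18 were higher, among them Mdm2 (0.92 ± 0.09), Ccng1 (0.93 ± 0.06), Sulf2 (1.10 ± 0.08) and Plk2 (1.11 ± 0.11), and 1 was lower, Perp (-0.68 ± 0.10). That p53 was more active in these livers is a candidate explanation and stays a hypothesis. Whether the drug or the diabetes it induces lay behind it was not tested, since no group of this design separates them.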
